A study of Mytilus edulis with 52 samples.

How the data were processed

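Total RNA from the gill of Mytilus edulis was hybridized by the study to 1-colour (Cy3) oligonucleotide arrays, 1 mussel per array, 52 arrays in 13 groups of 4. Mussels of 50 to 60 mm were held for 8 days at 11 °C and then exposed to 61.26 µg per l Cd, 111.68 µg per l Pb, both, or neither. Per the labels, replicates are separate mussels.

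Per the file headers, the scanner files hold the fluorescence intensity of each of 13925 spots as processed signal, background-subtracted and spatially detrended on a linear scale and not normalized between arrays, with spots not above background set to a small positive value. The headers give Agilent Feature Extraction 10.7.1.1, and the submitters' notes give 9.5.1. The same files hold the median pixel intensity of each spot and of its local background, and flags of 0 or 1, another kind of value, for spots well above background, saturated or non-uniform. The deposited value table by the authors is on a log2 scale and was quantile normalized in 3 sets, with medians of 6.76 for the initial and week 1 arrays, 6.24 for week 2 and 7.11 for week 4. When checked, 50 of its 52 columns matched their own scanner file (rank correlation at least 0.9996). The columns of initial replicate 3 (0.849) and week 4 control replicate 3 (0.924) did not, where different arrays had a median of 0.861. The table served only as an alternative, and not for comparisons of week 2 or week 4 with initial mussels, which cross its sets.

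The main values were the log2 of the processed signal minus the log2 of the array's 75th percentile over all non-control spots. Spots of the same probe were averaged after leaving out non-uniform spots (0 to 685 per array). A probe was tested when well above background on at least 4 of the 52 arrays, which kept 10066 of 12889 probes (78.1%) for 2864 of 3223 targets. The 75th percentile scaling left the median log2 change of all tested probes beyond 0.1 in 10 comparisons, and changes are to be read relative to it. It was 0.26 for week 1 Pb, -0.13 for week 2 Pb, 0.12 for week 4 Pb, -0.18 for week 2 mixture and -0.15 for week 4 mixture against control. It was -0.30 for week 1 and -0.14 for week 4 control against initial. It was -0.11 for mixture against Cd and -0.21 for mixture against Pb, and the difference of the mixture from the sum had -0.24.

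Groups were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with 1 mean per group over all 52 arrays (39 residual degrees of freedom), lmFit, contrasts and eBayes, 2-sided. The contrasts were each exposure against control at weeks 1, 2 and 4 and averaged over the 3 weeks, control against initial at each week, the exposures against each other, the mixture against the sum of Cd and Pb, and an F test of exposure by week. The p-values were adjusted over all tested probes by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Each adjusted p given is from limma, each interval is at 95%, and SDs are between mussels. Where no array of a group was well above background, the fold is a lower bound, written "at least": each value of that group was first raised to the lowest value that passed as well above background on the same array.

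The rule for named targets was set before the data were examined. Probes of metallothionein, a metal-binding protein, were to be given always, but no ID carries a name, so none could be picked out. For arrays without annotation the rule gives up to 2 higher and 2 lower IDs per comparison by largest change, 1 probe per target. A further 4 targets followed over all comparisons on their brightest probe (AJ005456.1, Contig20, AM879928.1 and GT157912.1) were chosen after their values were seen. The rule named AJ005456.1 and Contig20 as well, and AM879928.1 only for Cd against Pb, on another of its probes. The 24 gene lists fixed beforehand could not be tested, since 0 had members among the IDs.

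The method was tested on simulated data with 200 changed probes among 10066. The simulated noise was normal and independent between probes and arrays, without differences in brightness, saturation or slide. Its recovery and false calls therefore need not hold for the real arrays. For week 1 Cd it recovered 16.4%, 43.3% and 59.1% of the probes changed by 1, 2 and 3 log2 units, with 7 false of 86 calls. For Cd averaged over the 3 weeks it recovered 38.8%, 67.2% and 89.4%, with 6 false of 136 calls.

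Alternatives set beforehand were median scaling, quantile normalization, normexp background correction (offset 50) with quantile normalization, the authors' values, no filter on dim probes, a filter at 26 arrays, slide as a fixed block, a replicate block, a fit of the compared arrays alone, array weights, a trended robust variance and leaving out each array. The files have no mean signal, so the normexp alternative used the median signal. Alternatives chosen after seeing the data were slide as a random block, the number of detected probes as a covariate, the mean of each target's probes, and fits without the 4 arrays that failed the scanner's grid check, without the 2 arrays with mismatched columns, and without saturated probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Metal contents of tissue were not analysed here.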

Results

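Gill RNA of 52 blue mussels (Mytilus edulis) was measured on 1-colour oligonucleotide arrays, with 1 mussel per array. The mussels fall into 13 groups of 4. One group was sampled before exposure (initial). The other groups were sampled after 1, 2 or 4 weeks in seawater without added metal (control), with 0.54 µM cadmium (Cd), with 0.54 µM lead (Pb), or with both metals at these levels (mixture). Cd and Pb are toxic metals without a known role in the gill, a tissue in direct contact with the water. The mussels were not fed during the exposure. The arrays carry 12889 probes for 3223 transcript targets, with 4 probes for 3222 of the targets, and 10066 probes were well above background on at least 4 arrays and were tested. The files do not pair the target IDs with gene names, and 0 of the 3223 IDs matched the reference gene table, so each target is given by its ID.

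The arrays differed in brightness. Between 2706 and 9673 probes per array (median 7277.5) were well above background, the intensity at the 75th percentile ran from 325 to 3314, and 163 to 768 probes per array were saturated. Initial arrays had 6086 ± 1599 probes well above background (SD, n = 4), week 1 control arrays 8516 ± 483 and week 1 Pb arrays 5944 ± 1418. Values below are log2 intensities minus the log2 75th percentile of the same array. The labels do not give the number of tanks per exposure, so tank and exposure cannot be told apart, and the number of arrays limits the precision. Groups were also spread unevenly over the 7 slides. Slide 1 held only the initial and the week 1 Pb arrays, and slide 6 only the week 2 control and week 2 Pb arrays.

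The first question was which transcripts Cd alone changed in the gill. Target AJ005456.1 was far higher in Cd than in control mussels at every week. Its brightest probe averaged 5.39 ± 0.73 (SD, n = 12) in Cd and -2.20 ± 1.49 (n = 12) in controls, a log2 difference of 7.59 (95% interval 6.66 to 8.52), or about 192-fold. All 12 Cd arrays lay above the control mean (limma, adjusted p = 1e-15). The difference was 8.59 at week 1 (385-fold, adjusted p = 1.6e-09), 7.62 at week 2 (adjusted p = 5.7e-08) and 6.56 at week 4 (adjusted p = 3.1e-06), with 4 of 4 Cd arrays above the control mean each time. The effect of exposure on this probe was not shown to differ between weeks (F = 0.87, adjusted p = 0.98). The probe was saturated on 3 of the 12 Cd arrays, 1 of 4 at each week, and on 0 of the 12 control arrays, so these sizes and folds are not exact. Of the target's 4 probes, 3 passed the threshold, and all 4 differed upwards, by 1.56 to 7.59. Within slide 2, 4 Cd arrays exceeded 3 control arrays of week 1 by 8.44, and within slide 5, 1 Cd array exceeded 1 control array of week 4 by 5.92. With slide as a fixed block, the week 4 difference was 5.69 and no longer passed (adjusted p = 0.098), while week 1 gave 8.44 (adjusted p = 6.2e-08).

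**Figure D1:**
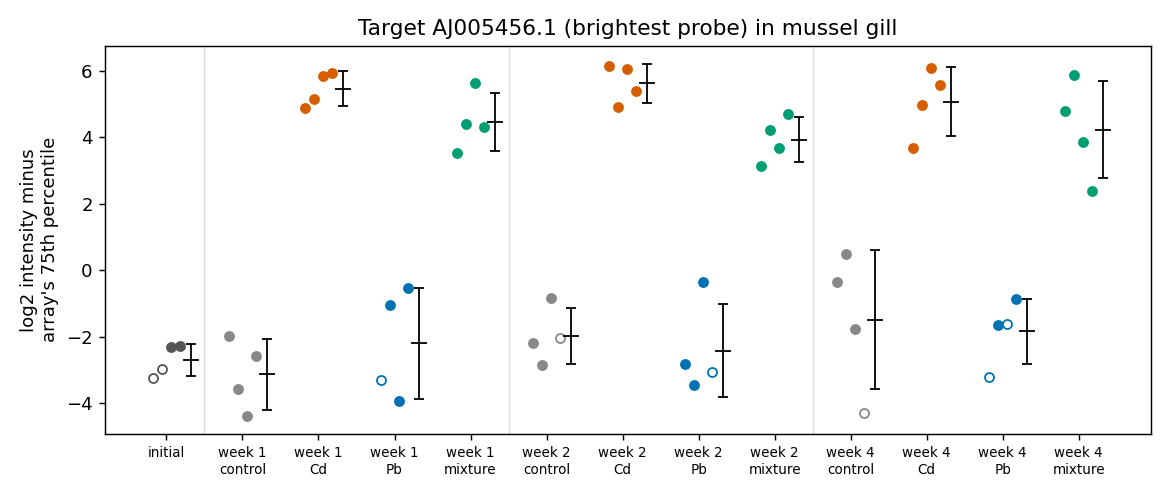
Scaled log2 intensity of the brightest probe of target AJ005456.1 (y axis, log2 intensity minus the array's 75th percentile) for each of the 13 groups (x axis), with 1 point per mussel, open where the spot was not well above background, and bars for the mean ± SD (n = 4). The Cd means lie between 5.08 and 5.63, the mixture means between 3.93 and 4.47, and the control, Pb and initial means between -3.13 and -1.48.

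Averaged over the 3 weeks, only the 3 probes of AJ005456.1 passed the threshold in Cd, and 561 probes had an unadjusted p under 0.05. Contig20, named after its values were seen, was 1.68 higher in Cd on its brightest probe and 12 of 12 arrays lay above the control mean, but it did not pass (adjusted p = 0.14). That probe was saturated on 6 of 12 Cd and 0 of 12 control arrays, so the size is not exact and the failure to pass does not rule out a change. At week 1, 4 probes were higher and 0 lower (418 at unadjusted p under 0.05). They included 1 probe of GT157917.1, at least 35.1-fold higher in the Cd mean (adjusted p = 0.0032), with 4 of 4 Cd arrays above the control mean and no control array well above background. Week 1 control was the lowest group for this probe (-7.95), with week 1 Cd at -0.98, initial at -4.06 and week 1 Pb at -2.62. At week 2 Cd stood at -3.46 and control at -2.55, and at week 4 they stood at -3.59 and -3.74. Only 1 of the 4 probes of GT157917.1 passed, the lowest change among them was 0.55, and quantile normalization gave a log2 change of 5.30 that did not pass (adjusted p = 0.09). At week 2, 3 probes were higher and 7 lower. AM881989.1 was 1.72 higher (adjusted p = 0.048), and Contig55 was 1.95 lower (adjusted p = 0.028) and AM877668.1 1.91 lower (adjusted p = 0.016), each in 4 of 4 arrays and on 1 of 4 probes. Contig55 stood at -0.99 in week 2 Cd and 0.96 in week 2 control, and at -1.7 in initial, -1.3 in week 1 control and -1.19 in week 4 control mussels. AM877668.1 stood at 0.96, 2.87, 1.35, 1.04 and 0.66 in the same groups. Week 2 control was thus the high group, on slide 6 with Cd on slide 7, so slide and exposure cannot be told apart there. The calls of AM881989.1 and Contig55 were kept in 10 and 13 of 22 alternatives. At week 4, 7 probes were higher and 0 lower (710 at unadjusted p under 0.05), among them Contig404, 2.32 higher in 4 of 4 arrays (adjusted p = 0.021), on 1 of 4 probes and kept in 15 of 24 alternatives. The week 2 split was 2 higher and 0 lower with median scaling and 17 higher and 23 lower with normexp background correction, and week 4 left 0 probes with slide as a fixed block. Leaving out 1 array moved the count to 8 at week 1 (Cd replicate 3), to 2 at week 2 (control replicate 3, Cd replicate 5 or Cd replicate 6), and at week 4 to 3 (Cd replicate 2), to 4 (control replicate 3, control replicate 6 or Cd replicate 1) or to 15 (control replicate 1 or Cd replicate 4). For the mean of the 3 weeks it moved to 5 (week 1 Cd replicate 7 or week 4 control replicate 3) or to 8 (week 4 control replicate 6).

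The same question was asked of Pb alone. Targets AM879928.1 and GT157912.1, named after their values were seen, were both higher in Pb. Averaged over the 3 weeks, the brightest probe of AM879928.1 was 5.44 ± 0.46 (SD, n = 12) in Pb and 4.35 ± 0.54 (n = 12) in controls, a difference of 1.09 (95% interval 0.76 to 1.42), or about 2.13-fold, and that of GT157912.1 differed by 1.11 (0.78 to 1.44). For each, 12 of 12 Pb arrays lay above the control mean, all 4 probes passed, and the adjusted p was 8.9e-05. At week 1 they stood at 5.65 and 5.71 in Pb, at 5.78 and 5.83 in initial mussels on the same slide, and at 4.74 and 4.73 in control. These week 1 differences of 0.91 and 0.97 did not pass, and quantile normalization gave 0.35 and 0.46. Slide and Pb cannot be told apart at week 1, and a fixed slide block could not be fitted for the mean of the 3 weeks. Both probes were saturated on 2 of 12 Pb and 1 of 12 control arrays, so the sizes are not exact. AM882410.1 rose by 1.42 (11 of 12 arrays, adjusted p = 0.014) and AM878856.1 by 2.09 (12 of 12 arrays, adjusted p = 0.037). AM878856.1 was well above background on only 4 of 12 Pb and 2 of 12 control arrays, 1 of its 4 probes passed, quantile normalization gave 1.53 (adjusted p = 0.17), and the call was kept in 14 of 38 alternatives. AM880629.1 fell by 0.94 (9 of 12 arrays, adjusted p = 0.03) and AM879240.1 by 0.88 (11 of 12 arrays, adjusted p = 0.0036), each on 1 of 4 probes, and with median scaling they changed by -0.95 and -0.89 and did not pass (adjusted p = 0.22 for both). Both fell most at week 1, where Pb mussels shared slide 1 with the initial ones. AM880629.1 stood at -3.34 in week 1 Pb, -2.27 in initial and -1.54 in week 1 control mussels, and AM879240.1 at -3.25, -2.82 and -1.84. Later, AM880629.1 was at -1.27 in Pb and -0.62 in control at week 2 and at -0.97 and -0.61 at week 4. AM879240.1 was at -1.90 and -0.77 at week 2, all on slide 6, and at -1.50 and -1.39 at week 4. In all, 25 probes were higher and 4 lower, and 824 had an unadjusted p under 0.05. Quantile normalization gave 25 higher and 13 lower, and normexp background correction gave 17 higher and 12 lower. With the number of detected probes as a covariate the balance reversed, to 26 higher and 38 lower. AJ005456.1 was not shown to change in Pb (0.05, 95% interval -0.89 to 0.98, adjusted p = 0.99), with 6 of 12 arrays above the control mean.

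At week 2 in Pb, 23 probes for 10 targets were higher and 5 were lower by adjusted p, while 645 had an unadjusted p under 0.05. AM882410.1 was 3.01 higher, with all 4 probes past the threshold (adjusted p = 0.0043), and AM879007.1 was 3.75 higher (adjusted p = 0.049), both in 4 of 4 Pb arrays. AM879007.1 passed on 1 of 4 probes and was well above background on 1 of 4 control arrays, and with quantile normalization it did not pass (3.21, adjusted p = 0.059), the call being kept in 9 of 23 alternatives. Week 2 control was the low group for its probe (-4.7), with initial at -0.67, week 1 control at -0.29 and week 4 control at -0.39. Week 2 Pb stood at -0.95, Cd at -1.28 and mixture at -0.35. AM879928.1 was 1.67 higher and GT157912.1 1.60 higher (adjusted p = 0.0035 for both). The 8 arrays of week 2 Pb and control shared slide 6. D14731.1 was at least 22.5-fold lower (adjusted p = 0.029) and Contig8 at least 21.3-fold lower (adjusted p = 0.049), with no Pb array well above background. D14731.1 passed on 2 of 4 probes and Contig8 on 1 of 2, and the calls were kept in 14 and 11 of 22 alternatives. Week 2 control was the high group for both. D14731.1 stood at 0.79 there, and at -4.94 in initial, -5.88 in week 1 control and -6.67 in week 4 control mussels. Contig8 stood at 0.71, -4.93, -6.7 and -7.12 in the same groups. Quantile normalization gave 25 higher and 11 lower, and median scaling gave 9 higher and 5 lower. Leaving out 1 array moved the count of 28 to 3 (control replicate 3), 7 (Pb replicate 1), 14 (Pb replicate 3), 15 (control replicate 1) or 17 (Pb replicate 5), and a fit of these 8 arrays alone gave 0.

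At week 1 in Pb, limma called 0 probes higher and 1 lower, with 1101 at unadjusted p under 0.05. The called probe of AM880773.1 fell by 2.26 (4 of 4 arrays, adjusted p = 0.0012), while the target's other probes differed by -0.12, -0.10 and -0.02. The same probe stood at -2.13 in week 1 Pb and -2.05 in initial mussels, the 2 groups of slide 1, and at 0.13 in week 1 control. Quantile normalization gave 2 higher and 8 lower at week 1, and normexp background correction gave 3 higher and 3 lower. Without week 1 control replicate 1 the count was 360 (346 higher, 14 lower), without Pb replicate 2 it was 188 (175 higher, 13 lower), without Pb replicate 4 it was 5, and without control replicate 3 or Pb replicate 6 it was 2. At week 4 limma called 0 probes, with 1055 at unadjusted p under 0.05, 5 probes under quantile normalization, 177 with array weights (155 of them lower) and 325 with the number of detected probes as a covariate (295 lower). With fewer probes under unadjusted 0.05 at week 2 than at weeks 1 and 4, the counts do not place the Pb response in 1 week. The unadjusted counts do not measure that response alone, since Pb and control arrays also differed in brightness. Their mean log2 75th percentile was 9.14 and 10.43 at week 1, 9.54 and 8.9 at week 2, and 10.84 and 9.73 at week 4. Without week 4 Pb replicate 3 the count was 164 (154 lower), without control replicate 2 it was 63, and without control replicate 1 or Pb replicate 7 it was 1.

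**Figure D2:**
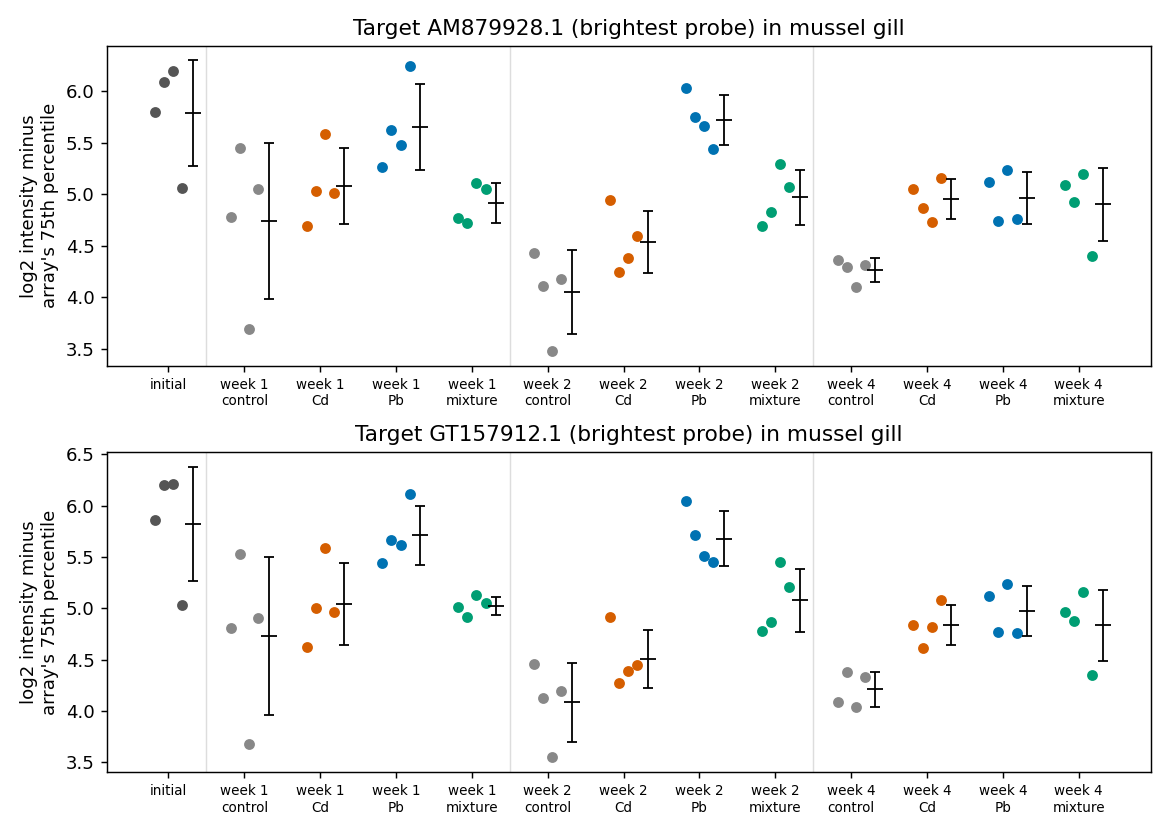
Scaled log2 intensity (y axis, log2 intensity minus the array's 75th percentile) of the brightest probe of AM879928.1 (upper panel) and GT157912.1 (lower panel) in the 13 groups (x axis), with 1 point per mussel and bars for the mean ± SD (n = 4). For AM879928.1 the week 2 Pb mean of 5.72 lies beside the initial mean of 5.78 and above the week 2 control mean of 4.05.

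The mixture addressed whether both metals together acted as each alone. Averaged over the 3 weeks, AJ005456.1 rose by 6.41 (95% interval 5.48 to 7.34), or 84.9-fold, in 12 of 12 mixture arrays (limma, adjusted p = 3.8e-13). Its mean was 4.21 ± 0.99 (SD, n = 12), and the weekly differences on that probe were 7.60, 5.91 and 5.71. The probe was saturated on 2 of 12 mixture arrays, so the fold is not exact. Contig20 rose by 1.67 (12 of 12 arrays, adjusted p = 0.016) with all 4 probes past the threshold. The probe was saturated on 4 of 12 mixture arrays, so the size is not exact. AM879928.1 rose by 0.58 (12 of 12 arrays, adjusted p = 0.035) and GT157912.1 by 0.64 (12 of 12 arrays, adjusted p = 0.018). The calls were kept in 20 and 34 of 39 alternatives, and the probes were saturated on 4 and 3 of 12 mixture arrays and on 1 of 12 control arrays each. Contig48 fell by 2.85 (adjusted p = 0.025) and AM880265.1 by 2.66 (adjusted p = 0.048), each in 10 of 12 arrays. With quantile normalization Contig48 changed by -2.94 (adjusted p = 0.097) and AM880265.1 by -2.73 (adjusted p = 0.14), changes as large that did not pass. Contig48 kept its call in 26 of 39 alternatives and AM880265.1 in 11 of 39. When probes saturated on at least 26 arrays were left out of the test, 5 named targets had the same changes but no longer passed, as the adjustment then ran over fewer low p-values. These were Contig20 (1.67, adjusted p = 0.096), AM879928.1 (0.58, adjusted p = 0.18), GT157912.1 (0.64, adjusted p = 0.12), Contig48 (-2.85, adjusted p = 0.14) and AM880265.1 (-2.66, adjusted p = 0.21), and these losses say nothing about saturation of those probes. With the main scaling, the 5 passes therefore depended on having the mostly saturated probes in the adjustment. With quantile normalization Contig20 (adjusted p = 0.0088), AM879928.1 (adjusted p = 0.0076) and GT157912.1 (adjusted p = 0.0016) passed. The fall of Contig48 was mainly at week 4, with means of 3.44 in control and -2.92 in the mixture, against 1.06 and -1.06 at week 1 and 0.15 and 0.06 at week 2. Within slide 5, 1 mixture array exceeded 1 control array of week 4 by 6.20 for AJ005456.1. With slide as a fixed block its week 4 difference was 4.84 (adjusted p = 0.13) and its week 1 difference 9.98 (adjusted p = 0.0021).

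The count for the mixture over the 3 weeks was 25 probes higher and 317 lower, and the lower ones were mostly saturated spots. Of the 317, 272 (85.8%) were saturated on at least 12 of the 24 arrays, against 4.3% of all tested probes, and 33 were saturated on none. Their median scaled change was -0.85 and their median unscaled change 0.03. The log2 75th percentile that was subtracted averaged 10.56 in mixture and 9.69 in control arrays, a difference of 0.87. Quantile normalization gave 16 higher and 1 lower, and normexp background correction gave 17 higher and 8 lower. Without the 396 probes saturated on at least 26 of the 52 arrays, 4 probes were higher and 4 lower. These were 3 probes of AJ005456.1, AM881738.1 (1.21 higher), 3 probes of GT157928.1 (-0.89, -0.92 and -0.95) and AM877767.1 (-1.11), the last 3 targets named after their values were seen. The count of 342 was 6 without week 1 control replicate 1, 152 without week 4 mixture replicate 5, 213 without week 4 control replicate 6 and 226 without week 1 control replicate 2.

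**Figure D3:**
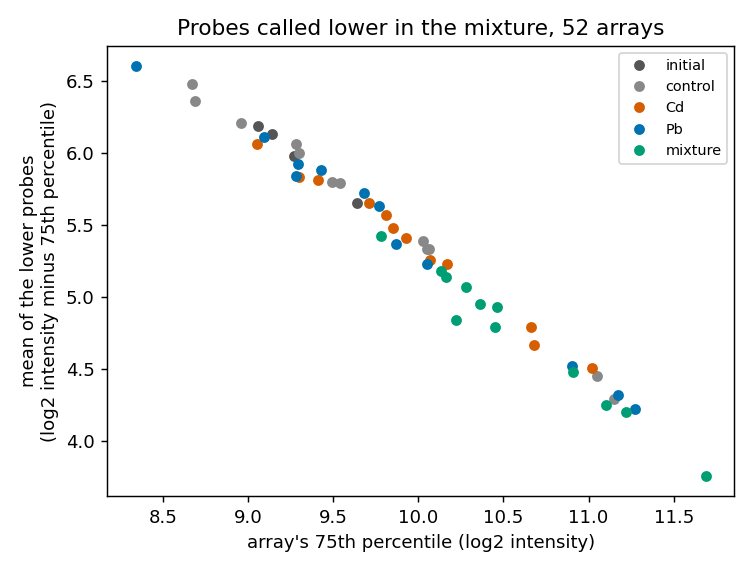
Mean scaled log2 intensity of the 317 probes lower in the mixture (y axis) against the log2 75th percentile of the array's intensities (x axis), with 1 point for each of the 52 arrays, coloured by exposure. The mean fell from 6.60 to 3.76 as the 75th percentile went from 8.34 to 11.69, and the mixture arrays lie towards the right.

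By week, AJ005456.1 was the target with the largest rise in the mixture at weeks 1, 2 and 4. At week 2, 9 probes were higher and 43 lower, and 0 of the 52 were saturated on 4 or more of the 8 arrays. AM880180.1 was 4.38 higher (adjusted p = 0.021), Contig461 fell by 6.73 (adjusted p = 0.045) and Contig41 by 3.00 (adjusted p = 0.02), each in 4 of 4 arrays. With quantile normalization Contig461 (-6.60, adjusted p = 0.084) and Contig41 (-2.96, adjusted p = 0.18) changed about as much but did not pass. Each had passed on 1 of 4 probes, and the calls were kept in 7 and 15 of 22 alternatives. The Contig461 probe was saturated on 1 of 4 control arrays, had an SD of 3.72 in control and was well above background on 2 of 4 mixture arrays. AM880180.1 had an SD of 2.8 in control, with 2 of 4 control arrays well above background, so both sizes are uncertain. Median scaling gave 4 higher and 4 lower at that week. Leaving out 1 array gave 26 (mixture replicate 6), 27 (mixture replicate 5), 33 (control replicate 1) or 34 (mixture replicate 2), and a fit of these 8 arrays alone gave 1. At week 1, 3 probes of AJ005456.1 were higher and 0 lower, with 340 at unadjusted p under 0.05, and 1 probe passed without mixture replicate 5. At week 4, 3 probes of AJ005456.1 were higher and 1 probe, of AM878516.1, was lower by 2.92 in 4 of 4 arrays (log2 change -2.92, adjusted p = 0.03). AM878516.1 was well above background on 1 of 4 mixture and 3 of 4 control arrays, and quantile normalization gave -2.26 (adjusted p = 0.34). Quantile normalization gave 10 higher and 7 lower at week 4, normexp background correction 7 higher and 6 lower, and median scaling 3 higher and 2 lower. With the number of detected probes as a covariate it was 15 higher and 152 lower. The week 4 count was 159 (149 lower) without mixture replicate 1, 33 without control replicate 2, 10 without control replicate 6, and 2 without control replicate 3, mixture replicate 2 or mixture replicate 4.

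**Figure D4:**
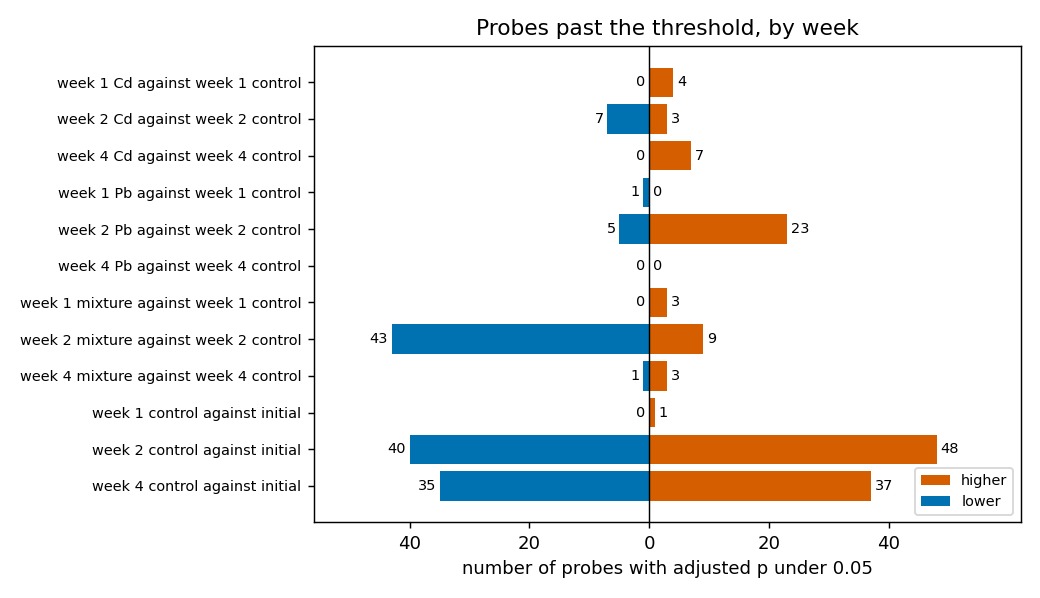
Number of probes with an adjusted p under 0.05 (x axis, lower to the left and higher to the right) for the 12 comparisons within a week or with the initial mussels (y axis), with 4 arrays per group and the count at the end of each bar. The counts run from 0 for week 4 Pb to 48 higher and 40 lower for week 2 control against initial.

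Comparing exposures directly over the 3 weeks, AJ005456.1 was 7.54 higher in Cd than in Pb (12 of 12 arrays, adjusted p = 1.3e-15) and 6.36 higher in the mixture than in Pb (12 of 12 arrays, adjusted p = 4.9e-13). It was 1.18 lower in the mixture than in Cd (log2 difference -1.18, 95% interval -2.11 to -0.25), but this did not pass (adjusted p = 0.31), and saturation on 3 of 12 Cd and 2 of 12 mixture arrays leaves the size of the difference uncertain. Contig20 was 2.01 higher in Cd than in Pb (12 of 12 arrays, adjusted p = 0.021) and 1.91 higher in the mixture than in Pb (12 of 12 arrays, adjusted p = 0.046). The second call was on 1 of 4 probes, kept in 16 of 38 alternatives, and that probe was saturated on 4 of 12 mixture, 2 of 12 Cd and 0 of 12 Pb arrays. AM879928.1, on 1 of its 4 probes, was lower in Cd than in Pb (-0.93, 11 of 12 arrays, adjusted p = 0.043), a call kept in 14 of 38 alternatives. AM880265.1 was lower in the mixture than in Cd (-3.97, 12 of 12 arrays, adjusted p = 0.045), and so was Contig48 (-3.83, 11 of 12 arrays, adjusted p = 0.045), but each of these calls was kept in only 14 of 39 alternatives. In all, Cd against Pb gave 11 probes higher and 1 lower, mixture against Cd 0 higher and 3 lower (1050 at unadjusted p under 0.05), and mixture against Pb 6 higher and 2 lower. Quantile normalization gave 19 higher and 7 lower for Cd against Pb, and 4 higher and 6 lower for mixture against Cd. Normexp background correction gave 2 higher and 6 lower for mixture against Cd, and a fixed slide block left 0. For mixture against Cd, 0 probes were left without any 1 of 20 of the 24 arrays, while 8 passed without week 1 mixture replicate 5 and 6 without week 2 mixture replicate 5. For mixture against Pb the balance turned over in several alternatives: 27 higher and 264 lower without week 1 Pb replicate 2 (291 in all), 17 higher and 240 lower without week 4 mixture replicate 1 (257), 25 higher and 292 lower with the filter at 26 arrays, and 71 higher and 511 lower with array weights.

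Whether the mixture differed from the sum of the effects of both metals was tested probe by probe. Contig23 alone passed, with 0 probes higher, 1 lower and 898 at unadjusted p under 0.05 (limma). Its change in the mixture lay below the sum by 2.28 on the log2 scale (log2 difference -2.28, 95% interval -2.99 to -1.57, adjusted p = 0.00085). Of the target's 3 tested probes, 1 passed here and 2 passed for mixture against Pb. All 3 lay below the sum (-2.28 to -1.5). Contig23 averaged 5.83 ± 0.81 (SD, n = 12) in Pb and 4.26 ± 0.86 (n = 12) in the mixture, a difference of -1.57 with 12 of 12 mixture arrays below the Pb mean (adjusted p = 0.00035). The probe was saturated on 8 of 12 Pb and 2 of 12 mixture arrays, and over the whole test on 12 of the 24 Cd and Pb and 6 of the 24 mixture and control arrays. The sizes and the interval are therefore not exact, and whether the difference from the sum holds without saturation is open. Quantile normalization gave -1.89 (adjusted p = 0.0042) for the difference from the sum. AJ005456.1 did not pass (-1.23, 95% interval -2.55 to 0.09, adjusted p = 0.57). Without week 1 mixture replicate 5 the count was 36 (33 lower).

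Across the 10066 probes, changes from control correlated between Cd and Pb (r = 0.58), Cd and mixture (r = 0.48) and Pb and mixture (r = 0.48). Probes are not independent replicates, and the 3 exposures share their control arrays. Simulated data with no effect and shared controls gave r = 0.48 (95% of simulations 0.26 to 0.69), and with the controls split between the exposures the correlations were 0.12, 0.03 and 0.07. Shared calls were 0 between Cd and Pb, 3 higher between Cd and mixture, and 11 higher and 1 lower between Pb and mixture. The shared controls raise such overlaps. When each exposure had its own 2 of the 4 controls of every week, the 3 calls of Cd and mixture were shared in all 216 ways of dividing the controls. Pb and mixture then shared calls in 40 of the 216 ways, with a median of 0 and at most 9, in fits with fewer controls per exposure.

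The time course of the unexposed mussels was measured against the initial ones. AM879928.1 fell by 1.73 by week 2 (adjusted p = 0.00021) and by 1.52 by week 4 (adjusted p = 0.0024), and GT157912.1 fell by 1.74 (adjusted p = 0.00021) and by 1.62 (adjusted p = 0.001), in 4 of 4 control arrays each time. With quantile normalization the week 4 fall of AM879928.1 did not pass (-1.12, adjusted p = 0.059). At week 1 they were at -1.04 and -1.09 and did not pass (adjusted p = 0.15 for both). By week 2, AM879007.1 had fallen by 4.04 (adjusted p = 0.013) and AM880666.1 by 2.74 (adjusted p = 0.0077), each in 4 of 4 arrays. In week 4 control AM879007.1 stood at -0.39, beside -0.67 in initial mussels, so its fall was not seen there. All 4 probes of AM879007.1 passed, but 2 of 4 of AM880666.1, whose probes ran from -2.74 to 1.40, so 1 of them rose. In group means, D14731.1 was at least 18.2-fold higher (adjusted p = 0.044) and Contig10 at least 7-fold higher (adjusted p = 0.049), calls kept in 11 and 12 of 21 alternatives. For D14731.1, 4 of 4 control arrays lay above the initial mean of -4.94. Control replicate 2 was at -3.73, below the highest initial array (-3), and the others were at 1.73 to 2.59. In week 4 control the same D14731.1 probe had a mean of -6.67, so its rise was not seen there. For Contig10, 3 of 4 arrays lay above the initial mean. By week 4, AM880180.1 had risen by 3.54 (adjusted p = 0.039), Contig383 had fallen by 3.78 (adjusted p = 0.045) and Contig276 by 2.80 (adjusted p = 0.033), each in 4 of 4 arrays. The Contig383 probe was saturated on 2 of 4 initial arrays and did not pass with quantile normalization (-3.19, adjusted p = 0.092), and the Contig276 probe was saturated on 1 of 4 control arrays, so these sizes are not exact. AM880180.1 was well above background on 2 of 4 initial arrays. Each of these 3 targets passed on 1 of 4 probes, and the calls were kept in 9 of 22 (AM880180.1), 10 of 22 (Contig383) and 12 of 21 (Contig276) alternatives. The called probe of Contig391 was 3.37 higher at week 4 in 4 of 4 arrays (adjusted p = 5.3e-05). The target's other 3 probes went down, by -2.5, -0.39 and -0.77 (log2). They were saturated on 4 of 4 initial arrays, so these sizes are not exact, and a rise of the whole target is not shown. The called probe was also low in week 1 Pb (-2.27), on the slide of the initial mussels (-2.06).

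In counts, week 2 controls had 48 probes higher and 40 lower than initial mussels, and week 4 controls 37 higher and 35 lower. Quantile normalization gave 56 higher and 29 lower at week 2, and 42 higher and 17 lower at week 4, where normexp background correction gave 40 higher and 12 lower. At week 1, 1 probe was higher and 0 lower, with 1145 at unadjusted p under 0.05, and it was the AM880773.1 probe (2.18, 4 of 4 arrays, adjusted p = 0.0025). Normexp background correction gave 1 higher and 2 lower at week 1. No slide held both initial and control arrays, so slide and time cannot be told apart in these comparisons. Leaving out 1 array gave 39 (initial replicate 2), 43 (initial replicate 5), 52, 55 or 57 (control replicates 1, 2 and 3) at week 2. At week 4 it gave 34 (control replicate 3), 37 (initial replicate 2), 40 (control replicate 1), 109 (control replicate 2) or 114 (control replicate 6). At week 1 it gave 385 (control replicate 1, 371 of them lower), 10 (control replicate 2) or 2 (initial replicate 3 or control replicate 5).

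A test of whether the effect of exposure differed between weeks passed for 2 probes, with 900 at unadjusted p under 0.05. For Contig391 (F = 10.92, adjusted p = 0.0029) the differences from control at weeks 1, 2 and 4 were -1.77, 0.36 and -0.75 in Pb, 1.65, -1.45 and -1.39 in the mixture, and -0.24, -0.98 and -0.83 in Cd. For AM880773.1 (F = 8.29, adjusted p = 0.032) they were -2.26, -0.02 and 0.20 in Pb. Week 1 Pb lay on slide 1 and week 1 control on slides 2 and 5. The count was 305 without week 1 control replicate 1, 273 without week 4 Cd replicate 2, 220 without week 4 Pb replicate 3, 188 without week 4 mixture replicate 5 and 167 without week 1 Pb replicate 2.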

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

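The tests on saturated spots, on the shared week 2 controls, on slides and on the remaining probes of a target were chosen only after the result was seen, and the tests on readings near background, on the number of detected probes and on other splits of the arrays were set before.

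Within groups, 6 of 111 sets of 4 values held a mussel far from the other 3, where chance gives about 5.6. Week 1 Cd replicate 4 had 8580 probes well above background, where the other 3 arrays had 8176 to 8209. Week 2 control replicate 2 was low for D14731.1 (-3.73, others 1.73 to 2.59), for Contig8 (-3.96, others 1.78 to 2.57) and for Contig10 (-5.61, others 0.58 to 1.48). Initial replicate 6 was at 3.23 for Contig383, where the others had 6.51 to 7. Week 4 control replicate 1 was at -4.38 for AM878516.1, where the others had -2.41 to -2.19. The effect of exposure differed between weeks for Contig391 (F = 10.92) and AM880773.1 (F = 8.29).

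The 317 probes lower in the mixture are a first pattern. Readings near background are argued against, since the lower probes were well above background on a median of 52 arrays, against 43 for all tested probes. The number of detected probes per array is argued against too, as 100% of the 317 kept an adjusted p under 0.05 with it as a covariate. Saturation is the explanation the values go with: 85.8% of these probes were saturated on at least 12 of the 24 arrays, and the median scaled change of -0.85 mirrors the difference of 0.87 in the log2 75th percentile. Most of these calls may therefore come from subtracting a higher percentile from spots that had reached the scanner's limit, while the 33 probes saturated on none of the arrays and an effect of the mixture on them stay open.

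A second pattern joins Pb and time: the 23 probes higher in Pb at week 2 had mostly fallen in week 2 controls (median -1.68 against initial mussels, 22 of 23 lower, 13 past the threshold), and week 2 Pb stood at the initial level (median 0.06). The week 2 controls enter both comparisons. In week 4 controls, which did not serve to pick them, 18 of the 23 probes were also lower, 11 of them past the threshold. The median of the 23 was -1.42 there, against -0.55 to 0.33 for 95% of 10000 random lists. These lists were matched on brightness and on probes per target, since the 23 probes stand for 10 targets. AM879928.1 and GT157912.1, which moved together and may be 1 transcript, each had all 4 probes among the 23. All 4 probes of each were also past the threshold in week 4 controls. The random lists drew their targets independently, so the interval does not allow for targets that move together. Other scalings gave medians of -1.50, -1.19 and -1.09. A slide difference between Pb and control is argued against, since all 8 arrays of week 2 lay on 1 slide. For control against initial, slide and time cannot be told apart, because no slide held both groups. As a hypothesis, transcripts that decline in unfed, unexposed mussels may decline less under Pb, but a tank effect and the slide of the initial mussels stay open.

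The third pattern is the pair of probes whose exposure effect differed by week. The initial mussels, which shared slide 1 with week 1 Pb and did not enter that test, were also low on both probes, with week 1 Pb minus initial at -0.21 for Contig391 and -0.08 for AM880773.1. For AM880773.1, a fall of the whole transcript in week 1 Pb is argued against, since 0 of its 3 other probes, saturated on none of the 8 arrays, were lower by more than 0.5. For Contig391 this stays open, because 0 of its 3 other probes were free of saturation. They stood 1.49, 1.36 and 0.93 above control in week 1 Pb, differences that saturation leaves uncertain. Slide 1 is a candidate explanation for the week 1 Pb values of both probes, and for the rise of AM880773.1 from initial to week 1 control. It does not cover the week 1 mixture, where Contig391 was 1.65 higher than control on different slides, and a sequence difference under a probe was not tested.

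Other splits of the same arrays set the counts against chance, without correction for the number of comparisons. A low share of splits argues against chance but does not exclude it. Of the 35 splits of 8 arrays, only the real one gave as many probes for week 2 Pb (1 of 35 splits, 28 probes, highest other 4) and week 2 mixture (1 of 35, 52 probes, highest other 1). It was also the only one for week 4 mixture (1 of 35, 4 probes, highest other 2) and week 4 control against initial (1 of 35, 72 probes, highest other 2). This is the smallest share that 35 splits can give. For week 2 mixture and week 4 control against initial, no slide held both groups, so these splits cannot tell exposure or time from slide. In week 2 Pb, week 2 mixture and week 4 mixture, the real split also parted the arrays by brightness. The log2 75th percentile was 8.67 to 9.28 in week 2 control, 9.29 to 9.77 in Pb and 9.78 to 10.36 in mixture. At week 4 it was 9.3 to 10.06 in control and 10.16 to 11.69 in mixture. For these counts the splits cannot tell exposure from brightness. Of 100 splits for the means of 3 weeks, the real one included, few gave as many probes as the real one for Cd (4 of 100, 3 probes, highest other 9), Pb (3 of 100, 29 probes, highest other 574) and mixture (1 of 100, 342 probes, highest other 229) against control. The same holds for Cd against Pb (3 of 100, 12 probes, highest other 1496) and mixture against Pb (1 of 100, 8 probes, highest other 4). For mixture against Cd it holds by the number of splits alone (3 of 100, 3 probes, highest other 84), since 0 of the calls were left without any 1 of 20 of the 24 arrays. With Cd, Pb, Cd against Pb and mixture against Cd, some other split called more probes than the real one.

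By the rule set beforehand, chance stays open for the counts of week 1 Cd (2 of 35 splits, 4 probes, highest other 278), week 2 Cd (2 of 35, 10 probes, highest other 190), week 4 Cd (2 of 35, 7 probes, highest other 52) and week 1 Pb (7 of 35, 1 probe, highest other 358). It stays open too for week 4 Pb (35 of 35, 0 probes, highest other 10), week 1 mixture (6 of 35, 3 probes, highest other 5), week 1 control against initial (10 of 35, 1 probe, highest other 1) and week 2 control against initial (2 of 35, 88 probes, highest other 481). The same goes for the mixture against the sum (6 of 100, 1 probe, highest other 120) and for exposure by week (6 of 100, 2 probes, highest other 274). Splits that called several times the real count, as for Cd at each week, Pb at weeks 1 and 4, week 2 control against initial, mean Pb, Cd against Pb, mixture against Cd, mixture against the sum and exposure by week, show differences between arrays that the groups do not describe. Looked at after the result, the split behind the 278 calls parted the arrays by brightness (log2 75th percentile 9.49 to 10.07 against 10.66 to 11.15), with 134 of the calls on probes saturated on at least 4 of the 8 arrays. The split behind 358 did the same (8.34 to 9.49 against 9.87 to 11.15, 318 such calls). The splits behind 190 and 481 parted them by detected probes (3929 to 5793 against 7593 to 8325, and 3856 to 6055 against 6955 to 7934). Those behind the 52 and the 10 calls at week 4 did neither, and brightness was not compared for the means of 3 weeks.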

How the results depend on the processing

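The alternatives with slide as a random block, the detected probes as a covariate, the mean of each target's probes, the arrays that failed the grid check, the mismatched columns and the saturated probes were chosen only after the results were seen. Of 1758 values of 57 named results under alternatives, 1351 kept their direction and their side of the threshold, 404 kept their direction and no longer passed, 3 newly passed and 0 reversed, and 16 named results held throughout. AJ005456.1 kept its call in all 39 alternatives for mean Cd (6.79 to 7.81, adjusted p 1.6e-16 to 2.1e-09) and for mean mixture (5.68 to 6.63). AM879928.1 (0.98 to 1.17) and GT157912.1 (0.99 to 1.20) kept theirs in all 39 for mean Pb, and Contig23 in all 63 for the difference from the sum (-2.43 to -1.89). AM880265.1 kept its call in 14 of 39 against Cd and 11 of 39 against control. Of 316 counts outside leaving out single arrays, 169 stayed within 1.5 times and 147 moved. The gene list alternatives were not run, a fixed slide block could not be fitted for groups on unlinked slides, and the authors' values were not used for weeks 2 and 4 against initial. Signal over background limits the dim probes, since 2706 to 9673 probes per array were well above it.

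In the counts, mean Cd, mean Pb and mean mixture stand for the exposure against control averaged over the 3 weeks, week 1 Cd and the like for an exposure against the control of that week, and week 1 control and the like for control against initial mussels. The cause of each move was not tested here. Median scaling gave 2 for week 2 Cd, 4 for week 4 Cd, 0 for week 1 Pb, 14 for week 2 Pb, 8 for week 2 mixture, 12 for mean Pb and 196 for mean mixture. It also gave 0 for week 1 control, 28 for week 2 control, 37 for week 4 control, 7 for Cd against Pb, 4 for mixture against Pb and 0 for exposure by week. Quantile normalization gave 2 for week 1 Cd, 37 for week 2 Cd, 21 for week 4 Cd, 10 for week 1 Pb, 5 for week 4 Pb, 1 for week 1 mixture and 17 for week 4 mixture. Further counts were 17 for mean mixture, 2 for week 1 control, 26 for Cd against Pb, 10 for mixture against Cd, 2 for mixture against the sum and 1 for exposure by week. Normexp background correction gave 2 for week 1 Cd, 40 for week 2 Cd, 6 for week 1 Pb, 2 for week 4 Pb, 13 for week 4 mixture, 9 for mean Cd and 25 for mean mixture. Then came 3 for week 1 control, 8 for mixture against Cd, 16 for mixture against Pb and 13 for exposure by week. The authors' values gave 8 for week 1 Cd, 36 for week 2 Cd, 20 for week 1 Pb, 45 for week 2 Pb, 5 for week 4 Pb, 10 for mean Cd and 23 for mean mixture. The rest were 20 for Cd against Pb, 6 for mixture against Cd, 6 for mixture against the sum and 1 for exposure by week. Without a filter on dim probes the counts were 17 for week 2 Pb, 58 for week 2 control, 0 for mixture against Cd and 1 for exposure by week. The filter at 26 arrays gave 23 for week 2 Cd, 11 for week 4 Cd, 5 for week 1 Pb, 11 for week 4 mixture, 3 for week 1 control, 115 for week 4 control and 317 for mixture against Pb. It also gave 11 for mixture against the sum and 161 for exposure by week. Slide as a fixed block gave 0 for week 4 Cd, 1 for week 4 mixture and 0 for mixture against Cd. A fit of the compared arrays alone, with fewer arrays behind the variance, gave 1 for week 2 Cd, 1 for week 4 Cd, 0 for week 1 Pb, 0 for week 2 Pb, 1 for week 1 mixture, 1 for week 2 mixture and 3 for mean mixture. Then came 0 for week 1 control, 6 for week 2 control, 0 for week 4 control, 3 for Cd against Pb, 11 for mixture against Cd and 5 for mixture against Pb. Array weights gave 38 for week 2 Cd, 3 for week 1 Pb, 87 for week 2 Pb, 177 for week 4 Pb, 339 for week 2 mixture, 15 for week 4 mixture and 538 for mean mixture. The rest were 28 for week 1 control, 232 for week 2 control, 256 for week 4 control, 8 for mixture against Cd, 582 for mixture against Pb, 29 for mixture against the sum and 298 for exposure by week. A trended robust variance gave 18 for week 2 Cd, 4 for week 1 Pb, 9 for week 4 mixture, 2 for week 1 control, 0 for mixture against Cd, 2 for mixture against the sum and 144 for exposure by week. Slide as a random block gave 21 for week 2 Cd, 4 for week 1 Pb, 2 for mixture against the sum and 6 for exposure by week. The number of detected probes as a covariate gave 9 for week 1 Cd, 325 for week 4 Pb, 167 for week 4 mixture, 64 for mean Pb, 274 for week 4 control, 0 for mixture against Cd and 9 for exposure by week. The mean of each target's probes, whose counts are of targets, gave 1 for week 1 Cd, 4 for week 2 Cd, 1 for week 4 Cd, 0 for week 1 Pb, 10 for week 2 Pb, 1 for week 1 mixture and 17 for week 2 mixture. Then came 1 for week 4 mixture, 1 for mean Cd, 8 for mean Pb, 81 for mean mixture, 0 for week 1 control, 17 for week 2 control, 13 for week 4 control, 4 for Cd against Pb, 0 for mixture against Cd, 4 for mixture against Pb, 2 for mixture against the sum and 0 for exposure by week. Without the 4 arrays that failed the grid check the counts were 0 for week 1 Pb, 3 for week 1 control, 0 for mixture against Cd, 4 for mixture against Pb and 1 for exposure by week. Without the probes saturated on at least 26 arrays they were 8 for mean mixture and 2 for mixture against the sum. Without the 2 arrays with mismatched columns they were 4 for week 4 Cd, 2 for week 4 mixture, 5 for mean Cd, 2 for week 1 control and 19 for week 4 control.

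Replicate numbers were checked as a possible pairing, over 19 pairs of an exposed and a control array with the same week and number. In 5 of these pairs the deviations from the group means correlated above 0.1, with a median of 0.01 (-0.20 to 0.25). Pairs with different numbers were not compared. The numbers were not taken to pair mussels. The replicate block gave 2 for week 2 Cd, 3 for week 4 Cd, 10 for week 2 Pb, 30 for week 2 mixture, 2 for week 4 mixture, 2 for week 1 control and 1 for exposure by week, and it kept 3 for mean Cd, 29 for mean Pb and 277 for mean mixture. The consensus correlation within slides was -0.008.

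Leaving out each array in turn gave 3 to 8 for week 1 Cd, 2 to 14 for week 2 Cd, 3 to 15 for week 4 Cd, 1 to 360 for week 1 Pb, 3 to 25 for week 2 Pb, 0 to 164 for week 4 Pb. The ranges were 1 to 3 for week 1 mixture, 26 to 46 for week 2 mixture, 2 to 159 for week 4 mixture, 3 to 8 for mean Cd, 22 to 34 for mean Pb, 6 to 435 for mean mixture, 1 to 385 for week 1 control. They were 39 to 68 for week 2 control, 34 to 114 for week 4 control, 3 to 15 for Cd against Pb, 0 to 8 for mixture against Cd, 5 to 291 for mixture against Pb, 1 to 36 for mixture against the sum, 1 to 305 for exposure by week. For 336 counts without a single array, 194 stayed within 1.5 times and 142 moved, mostly named beside the result. For Cd against Pb, by replicate number, it was 3 without week 1 Cd 4 or 7, week 1 Pb 4, 7 without week 2 Cd 2, week 2 Pb 1, week 4 Cd 1, week 4 Pb 1 or 2. For mixture against Pb, by replicate number, it was 5 without week 1 Pb 1, week 1 mixture 1 or 3, week 2 Pb 1, week 2 mixture 2 or 6, week 4 mixture 2, 15 without week 1 mixture 5, 257 without week 4 mixture 1, 291 without week 1 Pb 2. For mixture against Cd, by replicate number, it was 0 without week 1 Cd 2 or 3 or 4 or 7, week 1 mixture 1 or 3 or 7, week 2 Cd 3 or 5 or 6, week 2 mixture 2 or 4 or 6, week 4 Cd 1 or 2 or 4 or 7, week 4 mixture 2 or 4 or 5, 6 without week 2 mixture 5, 8 without week 1 mixture 5. For mixture against the sum, by replicate number, it was 2 without week 1 control 1 or 2, week 1 Cd 2, week 1 Pb 1, week 2 Cd 5, week 4 control 1 or 6, week 4 Cd 2, week 4 Pb 2, week 4 mixture 1, 3 without week 1 Cd 3, week 2 control 7, week 2 mixture 2 or 6, week 4 Pb 7, 4 without week 4 mixture 5. Above these, it was 5 without week 1 Cd 7, 9 without week 4 Cd 4, 36 without week 1 mixture 5. For exposure by week, by replicate number, it was 1 without week 1 Pb 1, week 1 mixture 3 or 5 or 7, week 2 control 2, week 2 Pb 1 or 3, week 2 mixture 2 or 6, week 4 Cd 4 or 7, week 4 Pb 1 or 7, 4 without week 1 Pb 6, week 2 Cd 5, 6 without week 4 Pb 2, 7 without week 1 control 2, week 2 Cd 2, week 2 Pb 5, week 4 control 1, 10 without week 2 mixture 4. Beyond these, it was 18 without week 1 Cd 2, 167 without week 1 Pb 2, 188 without week 4 mixture 5, 220 without week 4 Pb 3, 273 without week 4 Cd 2, 305 without week 1 control 1.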

Other observations

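The correlations of paired targets and the comparison with the probes of single targets were chosen only after the values were seen.

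Some of the most variable targets moved in a few mussels or groups. D14731.1 and Contig8 were high only in week 2 controls among the week 2 groups, with Contig8 at a mean of 0.71 in control, -4.55 in Cd, -5.78 in Pb and -4.77 in the mixture. On its brightest probe, Contig48 stood at 4.47 in week 4 control, 5.53 in Cd, 3.14 in Pb and -1.67 in the mixture. The SD within groups had a median of 0.89 and a 95th percentile of 2.19 over the tested probes.

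Targets that changed together may be 1 transcript listed under 2 IDs, which would make their changes 1 observation rather than 2. The deviations of D14731.1 and Contig8 from their group means correlated over the 52 arrays at r = 0.973 (rho = 0.968), those of Contig48 and AM880265.1 at r = 0.908 (rho = 0.834), and those of AM879928.1 and GT157912.1 at r = 0.860 (rho = 0.838). Without the 2 arrays farthest from the median, r was 0.969, 0.863 and 0.830. Each permutation p was 1e-05 for r and for rho, the smallest that 100000 permutations can give, and 1e-05 after adjustment over the 3 relations. Probes of the same target had a median r of 0.799 and a 75th percentile of 0.891 over 2637 targets. Random pairs of targets, matched on the number of arrays on which they were well above background, had a 99th percentile of 0.887, 0.717 and 0.792 for the 3 pairs, and all 3 pairs lay above it.

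All 3 pairs were left undecided. D14731.1 and Contig8 were well above background on a mean of 15.8 and 12.5 of the 52 arrays, and dim targets moved together in general (matched median r = 0.651), although r was 0.985 over the 14 arrays on which both were well above background. For Contig48 and AM880265.1, rho and the r without 2 arrays fell below 0.891, and for AM879928.1 and GT157912.1 r did as well. Co-regulated transcripts were not ruled out for any pair.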
